A study of Mus musculus with 30 samples.

How the data were processed

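Whole kidneys of male mice were dissociated with collagenase II, Pronase E and DNase I, red cells were lysed, and single cells were captured with 10x Chromium 3′ gel bead chemistry and sequenced on a NovaSeq instrument, per the labels' protocols. The db/db mouse carries a mutated leptin receptor gene and becomes obese and diabetic, and the db/m mouse is its lean control. The labels name 30 samples in 5 groups. They are lean db/m mice, db/db mice given vehicle, and db/db mice given the angiotensin receptor blocker (ARB) irbesartan at 20 mg/kg per day, the sodium-glucose cotransporter 2 inhibitor (SGLT2i) dapagliflozin at 3 mg/kg per day, or both drugs. Dosing lasted 8 weeks and mice were killed at 18 weeks of age. By their titles the samples are sequencing lanes of 16 libraries, with 2 for db/m, 4 for db/db with vehicle, 3 for ARB, 4 for SGLT2i and 3 for ARB+SGLT2i. Among the 4 db/db titles, db_dbCtrl12 and dbdbctrl12 carry the same animal number, and whether they are 1 mouse is not known. The db/db and db/m mice came from different suppliers, so genotype and supplier cannot be told apart in the design.

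The authors deposited 1 table of UMI counts per gene and cell barcode, not normalized. Cell Ranger 5.0.0 and build mm10 are named in the submitters' processing notes, and the annotation release and cell filters are not given in the sources used here. The table holds 83585 barcodes and 17336 genes with 432188796 counts. No barcode has fewer than 499 counts or 202 genes, and none has more than 49.99% of its counts from mitochondrially encoded genes. Each column name ends in a number that separates 15 sets of barcodes, with numbers up to 16 and 4 absent. That number appears in no label of any sample. No column could therefore be assigned to a library, mouse or group, and no mapping was inferred from order, size or values. The table was treated as 1 pooled sample. The planned edgeR, camera and permutation comparisons between groups were not run. No p-value, standard deviation or fold between groups is given.

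Cells with at least 200 genes and at most 50% mitochondrial counts were kept. Scrublet (scanpy 1.11.5) was run in each set with an expected doublet rate of 6%. Its automatic threshold called 100 barcodes, or 0.120% of all and at most 0.494% in any set, so the caller did not work as a doublet filter. These calls were removed and 83485 cells remained. Doublets must be assumed to be present in every class. Counts were scaled to 10000 per cell and log-transformed. Genes in at least 3 cells were used to pick 2000 variable genes (without mitochondrial, ribosomal and hemoglobin genes), and scaled values were limited to 10, and 30 principal components and 15 neighbours were used for Leiden clustering (leidenalg 0.10.2, resolution 1; Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0). Clusters were named from markers fixed before the data were examined, with at least 3 markers in 25% of the cells. Clusters with fewer than 20 cells stayed unnamed. A cluster in which several classes each had 3 markers in 10% of the cells, with a score of 0.5 or more, was split again. Sub-clusters with fewer than 2 of their own markers among the top 10 genes stayed unnamed. The splitting and sub-cluster rules were set after the clusters were seen. Barcode sets were not aligned to each other before clustering.

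Counts were summed over the cells of a class and scaled to a total of 1000000 (CPM), with exact 95% Poisson intervals. Shares have exact 95% binomial intervals (Clopper-Pearson). Both cover counting error only and say nothing of the spread between mice. The distal nephron level is the mean CPM, with equal weight, of the thick ascending limb-like, distal convoluted tubule-like, connecting tubule and principal cell-like and intercalated cell-like classes. Log2 ratios of proximal tubule to distal nephron add 1 to each CPM. Gene lists were fixed before the data were examined, and their members with 10 CPM or more on either side were counted. A list's median is set against 10000 random lists of the same size matched in 10 bins of expression, as a description and not a test. The rules for naming genes without group comparisons were written after the structure of the table was known and before expression by class was examined. They name the transporters and hormones chosen in the design, and for each list the 3 members highest in proximal tubule-like cells and the 2 with the largest and the 2 with the smallest ratio. Genes named outside this rule are marked in the text. Genes named by cluster or barcode set in the closing section were chosen after their values were seen. Values by set are given as a range and median. Counts of sets with a gene higher in the proximal tubule use only the thick ascending limb-like and distal convoluted tubule-like classes, which had 20 cells or more in every set.

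The ratios and list standings were tested on simulated data. Counts for 17336 genes were drawn for the comparison of proximal tubule with distal nephron, with 200 genes changed, and 100% of these had the right direction. The median absolute error was 0.19 for genes changed by a log2 ratio of 1 and 0.21 for those changed by 2. Poisson intervals held the true value for 96% of the changed genes, and 4 of 100 random lists stood outside the middle 95% of their own random lists. Those lists and their references were drawn from the same genes, so this checks the calculation only. It does not test the standing of lists of related genes. The simulation held no free RNA and no difference between mice. Alternatives were stricter cell filters (500 genes and 25% mitochondrial counts), doublet calls kept, and assignment of each cell by its marker score. Added after seeing the data were an uncentred marker score, removal of the 6% of barcodes with the highest doublet scores, clustering without the reported genes, and leaving out each barcode set in turn.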

Results

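Single-cell RNA counts were obtained from whole kidneys of lean db/m mice and of diabetic db/db mice given vehicle, irbesartan, dapagliflozin or both. The design asks how diabetes changes kidney cells, how each drug and the combination change the diabetic kidney, and whether the drugs together act additively. None of these comparisons could be made, nor that of SGLT2i with ARB, because the deposited table does not tie a cell to a library or group. By their labels the 30 samples were 2 from db/m, 8 from db/db with vehicle, 6 from ARB, 8 from SGLT2i and 6 from ARB+SGLT2i mice, as lanes of 16 libraries. No barcode set of the table could be assigned to a library, mouse or group, so the sets were not used as replicates, and the intervals cover counting error only. The table held 15 barcode sets of 3732 to 8567 barcodes, fewer than the 16 libraries, and it is not known whether libraries were merged or 1 is absent. The results describe the pooled cells, in which the proportion of lean, diabetic and treated kidneys is unknown. Total counts per set ran from 15275746 to 43459719, and the median UMIs per barcode of a set from 2396 to 7819.

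Proximal tubule-like cells dominated the suspension. They made up 73097 of 83485 cells, or 87.6% (95% interval 87.3 to 87.8%), and between 55.5% and 94.5% of a barcode set, with a median of 90.0%. Neutrophil-like cells were next at 4.30% (4.16 to 4.44%), but their share ran from 0.259% to 35.0% of a set with a median of 0.803%. The set with the highest neutrophil share was also the set with the lowest proximal tubule share, and without it the neutrophil share was 2.24%. Assigning each cell by a centred marker score, which puts the most common class near 0 by construction, gave a proximal tubule share of 32.2%. Distal convoluted tubule-like cells made up 3.30% (3.18 to 3.42%) and thick ascending limb-like cells 2.26% (2.16 to 2.37%). The distal convoluted tubule-like median over sets was 3.41%, above the neutrophil-like median of 0.803%. Neutrophil-like cells therefore rank next in the pooled cells but not by the median set. Macrophage, monocyte and dendritic-like cells made up 0.927%, T and NK-like cells 0.473%, intercalated-like cells 0.395%, endothelial-like cells 0.172% and connecting tubule and principal-like cells 0.0551%. The endothelial-like share was 0.294% with the stricter cell filter, 0.304% without the highest doublet scores and 0.103% when cells were clustered without the reported genes. The connecting tubule and principal-like share was 0.0910% with the uncentred marker score. With the centred score the shares of distal convoluted tubule, thick ascending limb, macrophage, intercalated, endothelial and connecting tubule-like cells were 6.21%, 6.44%, 5.25%, 1.69%, 1.43% and 5.12%. No cluster was named podocyte-like, the filtration barrier cell. The podocyte gene Nphs1 had 3 counts in all cells, so podocyte expression was not measurable in these data. A sub-cluster of 66 cells that met the rule for no class had Ren1, the renin gene, at 1333 CPM (1216 to 1459) and the smooth muscle genes Acta2 and Tagln at 1300 and 597 CPM, and these were chosen after their values were seen.

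**Figure D1:**
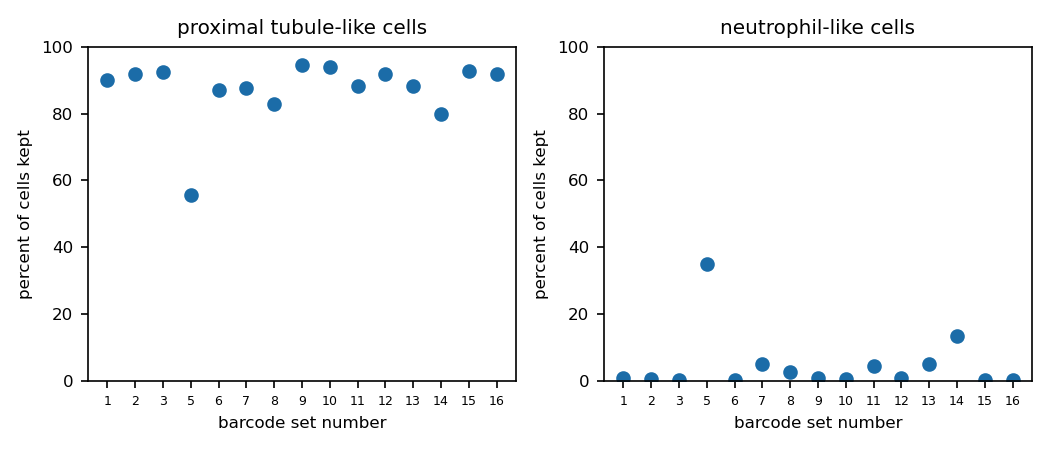
Percent of kept cells that were proximal tubule-like (left) or neutrophil-like (right) in each of the 15 barcode sets, 1 point per set, with set numbers on the horizontal axis. Proximal tubule-like cells made up 55.5% to 94.5% and neutrophil-like cells 0.259% to 35.0%, and the numbers carry no group.

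Slc5a2, which encodes the SGLT2 glucose cotransporter that dapagliflozin inhibits, was measured at 182 CPM in proximal tubule-like cells (95% interval 181 to 184). Its level was 31.4 CPM (27.6 to 35.5) in thick ascending limb-like cells, 33.3 CPM (30.04 to 36.9) in distal convoluted tubule-like cells and 41.1 CPM (36.7 to 46.0) in neutrophil-like cells, which are not known to use it. Slc2a2, the glucose exit transporter GLUT2, followed the same order with 105 CPM in proximal tubule-like cells (104 to 106) and 15.4 CPM (12.8 to 18.4) in thick ascending limb-like cells. Slc5a1, which encodes SGLT1, was instead highest in the thick ascending limb-like class of these at 86.8 CPM (80.5 to 93.4), against 32.4 CPM (31.8 to 32.9) in proximal tubule-like and 5.58 CPM (4.29 to 7.14) in distal convoluted tubule-like cells. Proximal tubule levels by set ran from 96.7 to 284 CPM for Slc5a2, from 12.0 to 48.9 CPM for Slc5a1 and from 18.0 to 141 CPM for Slc2a2. Slc5a2 was among the markers that named the proximal tubule class, so its position there is not a finding. In the mm10 annotation Slc5a2 lies on chromosome 7 from 128265657 to 128272430 and Slc5a1 on chromosome 5 from 33104219 to 33162870.

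Agtr1a, the angiotensin receptor gene whose product irbesartan blocks, was measured at 12.9 CPM in proximal tubule-like cells (12.5 to 13.2), against 1.60 CPM (0.854 to 2.74) in thick ascending limb-like and 1.77 CPM (1.08 to 2.74) in distal convoluted tubule-like cells. In the 147 cells of the cycling cell-like class it was higher, at 21.9 CPM (13.6 to 33.5) from 21 counts. Proximal tubule-like cells held 98.0% of Agtr1a counts and 98.0% of those of Slc5a2, in a class that held 91.2% of all counts. With the centred marker score these were 47.2% and 44.5%. Of the 12 renin-angiotensin genes at 10 CPM or more, 6 were over 2-fold higher in the proximal tubule than in the distal nephron and 3 over 2-fold lower. Ace, which makes angiotensin II, had a log2 ratio of 3.19 and Enpep 2.80. Agt, the angiotensinogen gene, was at 16.9 CPM (16.5 to 17.3) with a log2 ratio of 2.70. Nr3c2, the mineralocorticoid receptor gene, and Atp6ap2, the prorenin receptor gene, were lower with log2 ratios of -3.67 and -1.70, as was Mme, chosen after its values were seen, with -1.70. The list's median of 1.41 stood at the 100th percentile of random lists and was 0.34 with the centred marker score. Its summed level was nearly the same on both sides, at 671 CPM in the proximal tubule and 669 CPM in the distal nephron. It was highest in endothelial-like cells at 1960 CPM. Agtr1a lies on chromosome 13 from 30336441 to 30382867.

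**Figure D2:**
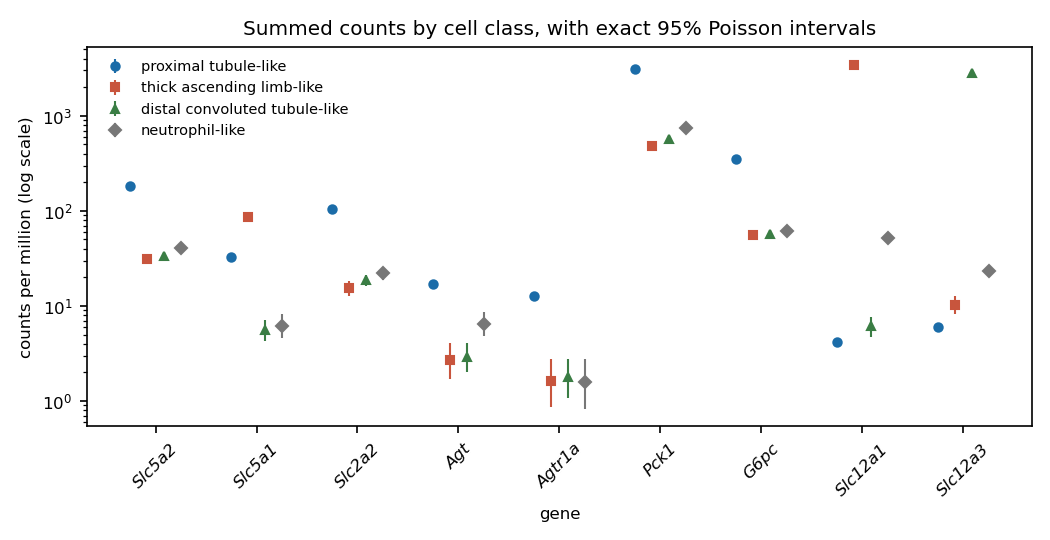
CPM on a log axis for 9 genes in 4 cell classes, as sums over all cells of a class with exact 95% Poisson intervals that cover counting error only. Slc5a2 stands at 182 CPM in proximal tubule-like cells and 31.4 CPM in thick ascending limb-like cells, and Slc5a1 at 32.4 and 86.8 CPM.

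Transcripts of proximal tubule cells were present in every other class. The 15 markers that named the proximal tubule class had a median log2 ratio of 3.02 over the distal nephron, with a range of 2.75 to 3.86. Ratios in this range are at the level of the naming markers themselves. Free RNA or mixed droplets could give such a level, but this was not tested in the distal classes. If they are the source, true ratios of such genes can be larger than the measured ones. Slc2a2 with 2.88, Pck1 with 2.83 and G6pc with 2.85, which were not among these markers, lay in this range. Slc5a2 was 1 of the markers.

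The gluconeogenesis list did not stand together as a whole. Of 17 gluconeogenesis genes, 8 were over 2-fold higher in the proximal tubule and 3 over 2-fold lower. Among the 8 were G6pc with a log2 ratio of 2.85 and, chosen after their values were seen, Slc37a4 with 2.40 and Pcx with 2.23. These 3 were higher in 15 of 15 sets. Eno1, within 2-fold, is also counted in the glycolysis list. Pck1 was at 3085 CPM (3080 to 3091), Fbp1 had a log2 ratio of 3.20, and both were higher in 15 of 15 sets. Fbp1 was also used to name the class. Got1 and Pck2 were lower with log2 ratios of -1.81 and -1.57, as was Ldhb, chosen after its values were seen, with -1.55. The list's median of 0.27 was at the 84.7th percentile, inside the middle 95% of random lists, and it was 1.05 when cells were clustered without the reported genes and 0.12 with the centred marker score. The clustering without the reported genes named no connecting tubule and principal cell-like class and left 4779 cells unnamed, so its distal nephron mean lacks that class, and the effects of clustering and of the changed mean on any list were not told apart. Glycolysis went the other way, with 8 of 14 genes over 2-fold lower, 1 higher and a median of -1.62 at the 0.01 percentile, which was -0.63 with the centred marker score. Hexokinase 1 (Hk1) and muscle pyruvate kinase (Pkm) had log2 ratios of -6.82 and -6.66, while Pklr, the liver-type pyruvate kinase gene, was higher with 2.83.

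Fatty acid oxidation genes stood higher in the proximal tubule, with 14 of 37 over 2-fold higher, 2 lower and a median log2 ratio of 0.64 above all random lists. The median was 0.12 with the centred marker score. Acaa1b and Acsm1 led with 3.05 and 3.04, and Ppargc1a, a regulator of mitochondrial number, and Hadhb were lower with -1.75 and -1.08. Of 8 ketone genes 5 were over 2-fold higher, with a median of 1.93 that was 0.12 with the centred marker score. Bdh2 and Slc5a8 had log2 ratios of 3.14 and 3.01, and Slc16a1, chosen after its values were seen, 2.54. All 72 nuclear oxidative phosphorylation genes lay within 2-fold and their median was -0.32, below all random lists and -0.19 with the centred marker score. Tricarboxylic acid cycle genes had 19 of 23 within 2-fold and a median of -0.23. Mitochondrially encoded genes had a median of -0.22, which became 0.062 with the stricter cell filter, -0.062 with the centred marker score and -0.34 when cells were clustered without the reported genes.

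Xenobiotic and steroid metabolism and organic solute transport had the highest medians. Of 33 organic solute transporters 27 were over 2-fold higher, 1 was lower and the median was 2.79, and of 22 genes of xenobiotic and steroid metabolism 20 were over 2-fold higher with a median of 3.00. These medians were 0.69 and 1.10 with the centred marker score. Glucose and ion transport had 12 of 26 genes over 2-fold higher and 9 lower, with Slc13a1 and Slc26a1 at 3.25 and 3.10 and the distal transporters Slc12a1 and Kcnj1 at -7.38 and -7.18. Its median was 0.60, against 0.22 with the centred marker score and 0.35 when cells were clustered without the reported genes. Antioxidant genes had 12 of 26 over 2-fold higher and 3 lower, which were Ephx1 at -2.93, Gsta4 at -2.74 and G6pdx, chosen after its values were seen, at -1.03, with Gpx3 at 23388 CPM and a log2 ratio of 2.73, and a median of 0.55 that was 0.17 with the centred marker score. Calcium, phosphate and vitamin D genes had a median of 0.55, with 4 of 11 over 2-fold higher and 4 lower, which was 0.019 with the centred marker score and 0.36 when cells were clustered without the reported genes. Lipid synthesis and storage had 8 of 17 genes over 2-fold higher and 3 lower and a median of 0.37, with G0s2 at 3.12 and Scd2 at -7.31. It was 0.69 without the highest doublet scores, 0.88 when cells were clustered without the reported genes and 0.83 without set 9. Cholesterol synthesis had 3 of 17 genes over 2-fold higher and 5 lower and a median of 0.25, with Fdps at -1.98, which was 0.068 with the uncentred marker score and had a counting interval of -0.032 to 0.44 that holds 0. The list of ribosomal protein genes, taken by symbol prefix, had a median of 0.45, with 84 of 87 within 2-fold, which was 0.040 with the centred marker score. The prefix also took in genes of other function, among them S6 kinase genes, and both members over 2-fold lower, Rps6ka1 and Rps6ka4, are such kinases.

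Tubule injury genes were lower in the proximal tubule-like class, with 12 of 18 over 2-fold lower, 1 higher and a median of -1.86, which was -0.82 with the centred marker score. Clu and Krt18 had log2 ratios of -7.20 and -6.28, and complement C3 was the exception with 3.25. Against the thick ascending limb and distal convoluted tubule-like classes alone, Clu and Krt18 were higher in proximal tubule-like cells in 0 of 15 sets. Cryab at -2.33 and Timp2 at -4.45, chosen after their values were seen, were so in 9 and 6 sets. These ratios compare cell classes and do not measure injury. The level of these genes in uninjured cells of each class is not known here. Havcr1, which encodes the injury marker KIM-1, was at 1.16 CPM (1.06 to 1.27) and ran from 0 to 24.2 CPM between sets with a median of 0.0951. Interferon response genes had 20 of 26 over 2-fold lower and a median of -1.73. It was -0.066 with the centred marker score, -0.30 when cells were clustered without the reported genes and -1.09 without set 6. Class II antigen presentation genes were over 2-fold higher for 6 of 6, with Cd74 at a log2 ratio of 2.74, but their summed proximal tubule level ran from 24.2 to 2795 CPM between sets with a median of 120. Their median log2 ratio was 2.74, and 0.29 with the centred marker score. The set with the highest class II sum, which also had the highest Havcr1 level, had the highest sum of immune and stromal markers in proximal tubule-like cells at 4413 CPM, against a median of 1114 CPM over sets, in a list that shares Cd74. In it the neutrophil gene S100a8 was at 819 CPM in these cells, against a median of 6.60 CPM, and macrophage, monocyte and dendritic-like cells made up 3.34%. The next highest class II sum was 1945 CPM in set 12, where S100a8 was at 8.03 CPM. Neutrophil-like cells made up 0.736% of set 12 and macrophage, monocyte and dendritic-like cells 1.20%. Its immune and stromal sum was 2299 CPM, of which Cd74 gave 1208 CPM. Inflammation genes had 5 of 9 over 2-fold lower and a median of -1.16, and -0.65 with the centred marker score. Immediate early and dissociation response genes, which enzymatic digestion can raise, had a median of -0.63 with 13 of 33 over 2-fold lower and 3 higher, and of -0.35 with the centred marker score. The 3 higher genes were Hspe1 at 1.37, Dusp1 at 1.28 and Cebpb, chosen after its values were seen, at 1.11.

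The unfolded protein and integrated stress response had a median of -0.52, with 19 of 20 genes within 2-fold, which turned to 0.064 with the centred marker score and was -0.26 when cells were clustered without the reported genes. Extracellular matrix and fibrosis genes had 1 of 10 over 2-fold higher, 4 lower and a median of -0.28, which turned to 0.28 with that score and to 0.066 when cells were clustered without the reported genes. Of the 4 lower genes, Tgfbr2 at -1.35, chosen after its values were seen, was higher in 15 of 15 sets against the thick ascending limb and distal convoluted tubule-like classes alone. The rest were so in 0 sets. Hypoxia genes had 1 of 14 over 2-fold higher, 5 lower and a median of -0.27, which was -0.010 with the centred score and -0.18 when clustered without the reported genes. The median of insulin and leptin signalling was -0.11 and took the other sign with the same settings, at 0.14 and 0.015, and it was -0.052 with the stricter cell filter and -0.023 without set 8. It had 4 of 20 genes over 2-fold higher and 8 lower. Its counting interval of -0.19 to 0.0047 holds 0. The median of mTORC1, autophagy and lysosome genes was -0.05, with 1 of 22 over 2-fold higher and 4 lower and a counting interval that holds 0. It was -0.0079 with the centred score, -0.0082 without the highest doublet scores, -0.011 without set 2 and -0.080 without set 16. Of the marker lists of other cells, the 8 markers of other epithelium were all over 2-fold lower with a median of -7.36. Against the thick ascending limb and distal convoluted tubule-like classes alone, which the counts of sets use, Fxyd4 was higher in proximal tubule-like cells in 15 of 15 sets, Atp6v1g3 in 6 and Aqp2 in 4. Fxyd4, Atp6v1g3 and Aqp2 were among the markers that named classes of the distal nephron mean, so their lower ratios are not a finding. Of the immune and stromal markers only 4 reached 10 CPM. Igfbp7, at 1016 CPM in proximal tubule-like cells and 1172 CPM in the distal nephron, made up most of their sum. In proximal tubule-like cells Cd74 followed at 205 CPM, S100a9 at 42.8, S100a8 at 38.7, Tyrobp at 3.73 and Lyz2 at 3.64 CPM. The 4 hemoglobin genes summed to between 0.0376 and 2563 CPM in proximal tubule-like cells of a set, with a median of 0.784.

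**Figure D3:**
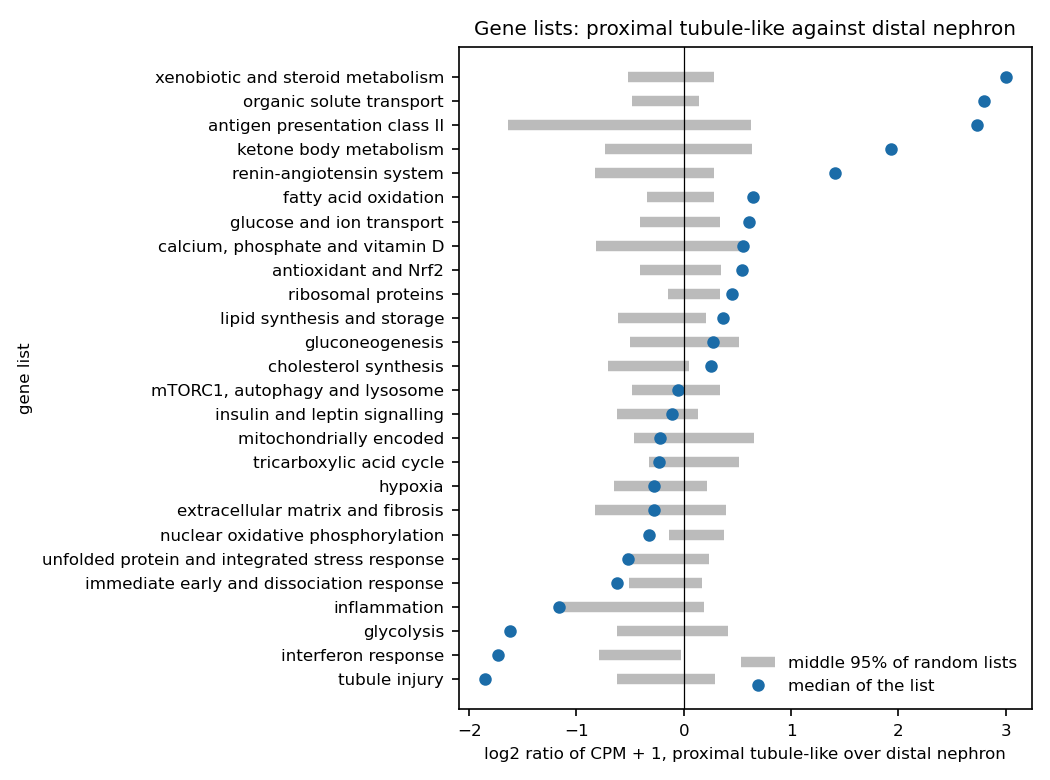
Median log2 ratio of proximal tubule-like to distal nephron CPM for the fixed gene lists with enough measured members, markers of other epithelium left out (points), with the middle 95% of 10000 matched random lists (bars). Xenobiotic and steroid metabolism stands highest at 3.00 and tubule injury lowest at -1.86.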

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

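No paired analysis was possible between the groups because no barcode set could be assigned to a mouse or group. Proximal tubule and distal nephron were compared within sets only as a count of sets, and a paired test over sets was not run. Without groups the intended changes of normalization, test, low-count filter, summed or separate libraries, sequencing lane, samples in the fit, gene set test and reversal were not run, and replicates could be left out only as barcode sets. The uncentred marker score, the removal of high doublet scores, the clustering without the reported genes and the left-out sets were chosen after seeing the data. Keeping the doublet calls, which changed only 100 barcodes, left 51 of 51 values within their counting intervals. The tally was 28 of 51 with stricter cell filters, 26 of 51 with the uncentred score and 3 of 51 with the centred score. It was 30 of 50 without high doublet scores, 20 of 49 when clustered without the reported genes and 660 of 764 with sets left out. Stricter cell filters gave a proximal tubule share of 90.1%, a neutrophil share of 3.43%, 98.2% of Slc5a2 counts in the proximal tubule, Slc5a2 at 166 CPM, and medians of 0.20 for gluconeogenesis and -2.24 for tubule injury, and turned the mitochondrially encoded median to 0.062. Assigning each cell by its centred marker score gave a proximal tubule share of 32.2%, a neutrophil share of 5.91%, 44.5% of Slc5a2 and 47.2% of Agtr1a counts in the proximal tubule, Slc5a2 at 192 CPM, and medians of 0.12 for gluconeogenesis, 0.12 for fatty acid oxidation and -0.82 for tubule injury. It turned the stress response median to 0.064 and the extracellular matrix median to 0.28. Centring puts the most common class near 0 by construction. The same score uncentred gave a neutrophil share of 4.93%, 98.8% of Slc5a2 and 98.5% of Agtr1a counts, and -2.40 for tubule injury. Removing high doublet scores gave a proximal tubule share of 87.9%, with 98.8% of Slc5a2 and 98.6% of Agtr1a counts. Clustering without the reported genes gave a proximal tubule share of 82.0%, 94.4% of Slc5a2 and 96.6% of Agtr1a counts, Slc5a2 at 181 CPM, and medians of 1.05 for gluconeogenesis and -1.70 for tubule injury. It turned the extracellular matrix median to 0.066 and named no connecting tubule and principal cell-like class, so the distal nephron mean changed with the clustering and their effects were not told apart. The report gives, beside each other list, the settings that moved its median by over 1.5 times. Beyond the constructions named, the cause was not tested. Leaving out 1 set at a time gave proximal tubule shares of 87.1 to 89.7%, neutrophil shares of 2.24 to 4.70%, Slc5a2 at 175 to 192 CPM with 97.9 to 98.1% of its counts, 97.8 to 98.2% of Agtr1a counts, and medians of 0.22 to 0.33 for gluconeogenesis, 0.61 to 0.73 for fatty acid oxidation and -2.34 to -1.76 for tubule injury. Classes of few cells limit what depth can show, with 46 connecting tubule and principal-like and 144 endothelial-like cells.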

Other observations

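In this part the tests of the highest Ren1 cell, of Ren1 without it and of how reference counts were spread over cells were chosen after the result was seen. Within the proximal tubule-like class, 13 clusters differed in the fixed lists. Cluster 14, led by Serpina1f and Slc7a12, had the highest summed level of organic solute transport genes at 6502 CPM, against a median of 3899 CPM over the clusters, and of renin-angiotensin genes at 1105 CPM against 684 CPM. Cluster 9, led by Fgg, Fga and Spp1, had the highest level of tubule injury genes at 9337 CPM against 1953 CPM. It also had the highest level of immune and stromal markers at 3769 CPM against 1261 CPM, and 59.3% of its cells came from set 5. Spp1 is a member of the injury list. In proximal tubule-like cells of set 5 it made up 8923 of the list's 11898.5 CPM. Cluster 7, with Pdk4, Btg2 and Krt20 among its top genes, took 99.8% of its cells from set 8, and cluster 11, with Iigp1 and Igtp among its top genes, took 69.8% from set 12. Clusters 6 and 10 took 51.7% and 50.6% of their cells from set 9, and 3 and 4 sets gave 10 or more cells to them. Clusters 6, 7, 9, 10 and 11 are therefore not described as cell types.

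Proximal tubule-like cells differed between barcode sets. The genes given here were chosen after 4639 genes, 29 lists and 51 genes listed by set had been examined, so they are extremes among many, and the set numbers carry no group. Kap was at 2402, 2178, 1196, 992, 3040, 5646, 8258, 23064, 26358, 9462, 3284, 4157, 1874, 3358 and 6891 CPM in sets 1, 2, 3, 5, 6, 7, 8, 9, 10, 11, 12, 13, 14, 15 and 16 in that order. Spp1, in the same order, was at 604, 540, 872, 8923, 590, 1030, 328, 81.4, 41.8, 352, 744, 469, 481, 425 and 499 CPM. Btg2 was at 3.23, 5.22, 3.74, 38.9, 2.10, 9.26, 1087, 1.38, 2.46, 2.83, 3.45, 3.52, 3.73, 3.30 and 7.49 CPM. The clock output gene Dbp was at 46.0, 9.01, 5.67, 3.78, 6.50, 3.17, 6.03, 8.46, 10.7, 82.1, 157, 17.5, 91.4, 73.7 and 15.8 CPM, and the clock gene Arntl at 2.72, 11.8, 17.8, 13.4, 19.1, 18.8, 4.73, 13.1, 9.52, 1.68, 0.746, 12.1, 2.00, 2.24 and 8.43 CPM. Across 4639 genes, centred profiles of sets 9 and 10 correlated at 0.89, the next pair at 0.57, and the median over 105 pairs was -0.08, where centring by itself gives a mean of -0.07. Genes are not independent replicates.

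Neutrophil-like cells held proximal tubule transcripts. Their 15 proximal tubule markers stood at 8.88% to 62.6% of the level in proximal tubule-like cells of the same set, with a median of 28.9%. If free RNA were the source, the markers would keep the ratios they have in proximal tubule-like cells, and the interquartile range of their log2 observed over expected counts was 0.31, under the bound of 1 set beforehand. Free RNA from proximal tubule cells is consistent with this, and mixed droplets would give the same ratios and stay open. No biological explanation was tested.

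Ren1, the renin gene, had 883 counts, of which 476 were in the unnamed sub-cluster of 66 cells with Ren1, Myl9, Acta2 and Tagln among its top genes, and 379 in 39 proximal tubule-like cells. Of these, 329 were in 1 cell of set 14 with 701 counts in all. Free RNA spread by depth would give 0.0105 there, even with that cell's own counts in the rate, so free RNA is an unlikely source for that cell. For the other 50 counts free RNA stays open, because the test of it turned out to be void. It set Ren1 against Slc12a1 and Slc12a3 in immune-like cells and gave lower bounds of the odds ratio of 28.2 with the highest cell, 4.94 without it and 1.32 without set 8 as well, which held 341 of the 742 reference counts, but these counts lay in 242 cells, where independent counts spread by depth would lie in 519 or more. For these 50 counts a renin cell placed in the wrong class, mixed droplets or low expression in the tubule also stay open. For the highest cell, 329 of 701 counts argue against low expression, while a misplaced renin cell or a mixed droplet stays open. No biological explanation was tested.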
